A study of Juglans regia with 21 samples.

How the data were processed

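Pellicle RNA of walnut cultivar Xinwen179, grown in a field, was measured by paired-end, strand-specific mRNA sequencing after poly(A) selection and rRNA removal, per the labels' protocols. The samples form 7 stages of 3 libraries, 21 in all. The labels' protocol text speaks of 16 libraries, and all 21 samples named by the labels were used. FastQC, HISAT2, Cufflinks and DESeq2 are named per the submitters' processing notes, without role, order or a usable version. The genome build, annotation and read counter are not given in the sources used here, nor whether counting used strand, so reads of near-identical copies and of overlapping or antisense genes may not be told apart.

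The deposited table holds whole-number read counts per gene and library for 31425 genes, per the file headers, not normalized by the authors. It also holds FPKM values, which the authors derived from these counts: count over gene length and column total gives each deposited FPKM with a largest relative deviation of 5.11e-15. FPKM was used for this check alone. No sample column was left unmapped. The table pairs gene IDs with NR and Swiss-Prot descriptions, which served as product names: NR where it names a product (16809 genes), else Swiss-Prot (6718), with 7898 genes left without a name. The separate reference gene table was not used here, as 0 of the IDs matched it. Of the genes, 5183 had 0 reads in all libraries.

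Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes passed filterByExpr by stage (minimum count 10), libraries were scaled by TMM, and a robust quasi-likelihood model with 1 coefficient per stage and no replicate term was fitted to all 21 libraries, so that the spread is shared over stages. The biological coefficient of variation was 0.102. An F-test compared the 7 stages, and 2-sided contrasts compared 19W with 8W and the 6 consecutive pairs. P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The standard error of a log2 change is its size over the square root of its F value. Levels are TMM-scaled CPM. TMM factors fell from 1.10 to 1.13 at 8W to 0.880 to 0.887 at 19W.

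The tests, the gene lists and the rule for named genes were fixed before the data were examined. For 19W against 8W the rule takes the 10 largest rises and 10 largest falls among called genes with at least 10 CPM in the higher stage and no overlap between the libraries of both stages, and for each consecutive pair the 5 largest of each. Genes without a product name are skipped. For each list it takes the 2 members with the most reads that changed over stages. SWEET15 and IAA29 fall under that last part. Where the lower stage had 0 reads, folds are bounds against a floor of 3 reads per library. With 1 to 3 reads, the ratio of means is given with an exact Poisson interval at 95% confidence.

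The 28 lists take genes by product name. They cover phenylpropanoid and lignin, flavonoid, shikimate and polyphenol oxidase enzymes, MYB, bHLH, NAC and WRKY regulators, cell wall, cutin, fatty acid and sugar enzymes, hormones, stress, transport, ribosomes and proteasome, and other tissue the samples could hold: embryo and kernel storage, late embryogenesis, photosynthesis and mitosis. The 27 with at least 5 tested members were tested with limma camera (preset correlation 0.01), adjusted over lists within a comparison. Of 44 calls, 4 held with an estimated correlation, all at 19W against 8W. Name matching took in some unlike members: cyclin-dependent kinases in the mitosis list, heavy metal transport genes in the transferase list, a lipid-transfer superfamily protein in the storage list.

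Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, no filter, a filter of 1 CPM in 3 libraries, a replicate block, fits of 6 libraries, leaving out each library, and, for peak stages, a 4-fold range. Replicate pairs within stages differed by more than sampling noise, with chi-square per degree of freedom of 3.07 to 27.0, so no pair was merged. In counts simulated for 19W against 8W over 21088 genes, edgeR recovered 31 of 50 genes raised 1.5-fold, 44 of 50 at 2-fold, 50 of 50 at 4-fold and 31 of 50 lowered to 0.5, with 3 unchanged genes called. Only these genes were changed, far fewer than between the real stages. That makes the adjustment stricter, so recovery in the real data may differ.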

Results

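The pellicle is the thin seed coat around the walnut kernel. Poly(A) RNA from pellicles of the *Juglans regia* cultivar Xinwen179 was sequenced at 7 stages, 8, 9, 11, 13, 15, 17 and 19 weeks after pollination (8W to 19W), with 3 libraries per stage. The series was set up to look for genes that change as the pellicle develops. Total read counts ran from 13144713 to 17878761 per library over the 21 libraries. The labels do not say whether the 3 libraries of a stage came from separate trees, so p-values measure the spread between these libraries, which may be technical. Counting intervals and read floors given with single genes cover counting error only. Levels are given as scaled CPM, mean ± SD with n = 3, and chromosome positions are those of the deposited table.

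Nearly all genes tested differed between the libraries of the 7 stages. Of 21707 genes tested, 21214 (97.7%) differed between stages in edgeR's quasi-likelihood F-test, and 16362 of these spanned at least 2-fold between their highest and lowest stage. At least 4-fold was spanned by 8444. Among the 16362 genes, 22.5% were highest at 8W, 16.2% at 9W, 13.4% at 11W, 9.20% at 13W, 7.24% at 15W, 18.4% at 17W and 13.2% at 19W. The transcript of the auxin-responsive protein IAA29 (Jr4DG00217000) stood at 3.18 ± 0.235 CPM at 8W and 3304 ± 40.9 CPM at 15W. The sugar transporter SWEET15 (Jr3DG00093800) went from 81.4 ± 7.37 CPM at 8W to 2614 ± 63.2 CPM at 19W. Each of the 21 libraries correlated best with a library of its own stage, with Spearman correlations across genes of 0.978 to 0.995 within stages and 0.717 to 0.953 between stages.

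**Figure D1:**
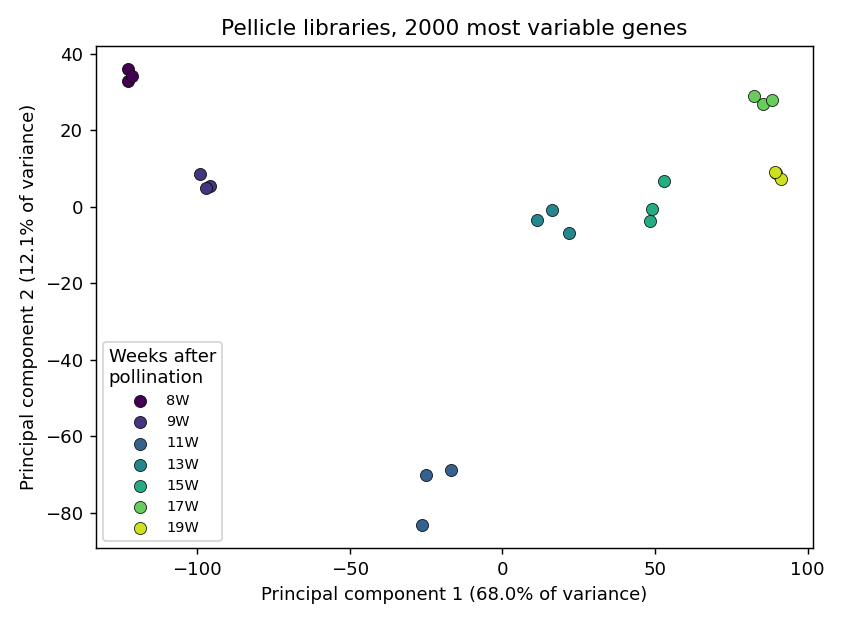
Each point is a library, placed by the first pair of principal components of log2 CPM over the 2000 most variable genes and coloured by weeks after pollination. Component 1 holds 68.0% of the variance and runs from 8W to 19W, and component 2 holds 12.1%, with the 3 libraries of 11W at its lower end.

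The comparison of 19W with 8W sets the last sampled stage against the first. Of the 10 largest rises named here, an 11S legumin and glutelin type-A 3 belong to the storage list, and an 18 kDa seed maturation protein to the late embryogenesis list. Both lists were fixed as markers of kernel tissue. Membership goes by product name, so seed or kernel genes under other names, also among these 10 rises, can lie outside both lists. The storage list rose in 14 of 17 members and fell in 2 (adjusted p = 0.000214, and adjusted p = 0.296 with an estimated correlation). An embryonic protein DC-8-like gene (Jr5SG00047500, chromosome 5S, 4518962 to 4520023), of the late embryogenesis type, had 287 ± 42.8 CPM at 19W and 0 reads at 8W, at least 1580-fold higher against a floor of 3 reads per library (adjusted p = 3.52e-10). Oil body-associated protein 1A (Jr1SG00075800, chromosome 1S, 15080628 to 15081817) reached 260 ± 9.61 CPM, at least 1430-fold higher. An 11S legumin, a seed storage globulin (Jr2DG00249900), rose from 0.198 ± 0.119 to 1761 ± 255 CPM, a log2 change of 13.03 ± 0.874 (SE). An 18 kDa seed maturation protein (Jr5DG00028300) rose from 0.185 ± 0.182 to 1649 ± 46.5 CPM. Its fitted log2 change was 13.08, and 13.97 without 8W replicate 1 or 12.48 without 8W replicate 3.

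The other large rises at 19W were a 48-kDa glycoprotein precursor (Jr4SG00109000; 1367 ± 125 CPM), peroxidase P7 (Jr2SG00129600; at least 499-fold), glutelin type-A 3 (Jr3SG00152400; at least 429-fold), the tonoplast aquaporin TIP3-2 (Jr8SG00074600; at least 415-fold) and an NADP-dependent glyceraldehyde-3-phosphate dehydrogenase (Jr8DG00158000; at least 345-fold). Alpha-dioxygenase 2 (Jr8DG00132200), with 1 read over the 8W libraries, was 13800-fold higher (95% counting interval 2350 to 516000). Among the largest falls, a GDSL esterase/lipase (Jr4DG00086200) went from 46.2 ± 5.16 CPM to 0 reads, at least 195-fold lower. AP2-like transcription factor ANT (Jr4SG00051100), a regulator of organ growth, was at least 99-fold lower. An ent-kaurenoic acid oxidase of gibberellin synthesis (Jr7SG00015200) fell from 204 ± 29.3 CPM to 2 reads over 3 libraries, 3960-fold (interval 1070 to 31900). A non-specific lipid-transfer protein (Jr5DG00093300) fell by 11.53 ± 0.391 (SE) on the log2 scale, from 336 ± 53.8 CPM. A lipid-transfer protein AP10-like gene (Jr5DG00092700) was 4610-fold lower (interval 809 to 178000). The DIR1 lipid-transfer gene (Jr3DG00054600), aspartic proteinase CDR1-like (Jr6DG00186500), a cucumisin-like protease (Jr1SG00178700), peroxidase 29 (Jr1DG00103600) and a glucan 1,3-beta-glucosidase (Jr3SG00025000) were at 0 reads at 19W and at least 94.7-, 184-, 163-, 149- and 108-fold lower. Leaving out 1 library moved some fitted folds by over 1.5 times. The log2 change of Jr4SG00109000, 13.37, was 12.77 without 8W replicate 1 and 15.08 without 8W replicate 3, and that of Jr8DG00132200, 13.17, was 14.92 without 8W replicate 3. Without 19W replicate 3 those of Jr5DG00092700, Jr7SG00015200 and Jr5DG00093300 went from -11.74, -11.70 and -11.53 to -13.81, -14.59 and -12.81.

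WRKY transcription factors, which include many stress and senescence regulators, rose as a group from 8W to 19W. Of 59 tested members 47 rose and 6 fell, with a median log2 change of 3.29, or 2.55 with members at 0 reads set to their bound (limma camera, adjusted p = 2.21e-08, and adjusted p = 0.049 with an estimated correlation). WRKY33 (Jr7DG00064100) rose from 36.6 ± 4.08 to 904 ± 28.5 CPM, and a second member (Jr5DG00087600) from 3.71 ± 1.38 to 360 ± 27.8 CPM. Of 77 NAC transcription factors 49 rose and 19 fell (adjusted p = 5.33e-07, and adjusted p = 0.0236 with an estimated correlation). NAC 21 (Jr6DG00175900) rose from 237 ± 5.93 to 1708 ± 29.2 CPM. NAC 35 (Jr3DG00093600) rose from 704.5 ± 29.6 to 1354 ± 111 CPM. Of 79 ethylene genes 54 rose and 13 fell (adjusted p = 1.63e-05, and adjusted p = 0.049 with an estimated correlation), ethylene receptor 2 (Jr1SG00119600) by 0.96 on the log2 scale. The ACC oxidase gene with the most reads (Jr2SG00187000) stood at 742 ± 37.9 and 856 ± 34.5 CPM and did not pass the test (adjusted p = 0.0818).

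Late embryogenesis and desiccation genes rose in 13 of 16 members and fell in 1 (adjusted p = 1.38e-05, and adjusted p = 0.0236 with an estimated correlation). Dehydrin ERD14 (Jr4DG00147900) rose from 301 ± 11.8 to 1751 ± 37.4 CPM and dehydrin 2 (Jr4SG00068600) from 126 ± 7.41 to 1270 ± 163 CPM. Of 17 embryo and kernel storage genes 14 rose and 2 fell, with a median log2 change of 7.90 (adjusted p = 0.000214, and adjusted p = 0.296 with an estimated correlation). Both lists were fixed as markers of tissue inside the seed coat, so either rise may come from such tissue. For the late embryogenesis list this was not tested. The summed level of the storage list was 311.5 ± 79.5 CPM at 8W, 1173 ± 186 at 9W, 18770 ± 8020 at 11W, 8980 ± 5320 at 13W, 10520 ± 1830 at 15W, 4834 ± 1280 at 17W and 21290 ± 2610 at 19W. The SD at 11W and 13W was wide beside the mean. A vicilin-like protein (Jr1DG00211500) stood at 42.0 ± 23.8 CPM at 8W and 10750 ± 1530 CPM at 19W, and Legumin B (Jr1DG00199500) at 76.3 ± 48.1 and 2667 ± 383 CPM.

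Of 72 secondary wall and cellulose synthesis genes 47 fell and 19 rose (adjusted p = 0.00781, and adjusted p = 0.209 with an estimated correlation). The members with the most reads went the other way: COBRA-like protein 7 (Jr1DG00161100) rose from 18.0 ± 1.94 to 237 ± 7.55 CPM and fasciclin-like arabinogalactan protein 17 (Jr5SG00019000) from 25.2 ± 0.651 to 147 ± 17.7 CPM. Of 134 cell wall loosening and pectin enzymes 71 fell and 37 rose (adjusted p = 0.0112, and adjusted p = 0.144 with an estimated correlation), while a beta-galactosidase (Jr2DG00209100) rose from 842 ± 134 to 3857 ± 146 CPM and xyloglucan endotransglucosylase 16 (Jr1DG00129000) by 0.61 on the log2 scale. The summed level of the wall loosening list was 7698 ± 500 CPM at 8W and 12900 ± 512 CPM at 19W. With library sizes alone as scaling, its call was lost (adjusted p = 0.0705). Of 135 cutin, suberin and wax genes 64 fell and 42 rose (adjusted p = 0.00781, and adjusted p = 0.0647 with an estimated correlation). Long chain acyl-CoA synthetase 2 (Jr3SG00147100) and a lipid-transfer protein-like gene (Jr3SG00156800) rose by 0.69 and 0.91 on the log2 scale. Of 120 DNA replication and mitosis genes 70 fell and 20 rose (adjusted p = 0.00781, and adjusted p = 0.46 with an estimated correlation). Histone H1 (Jr4DG00061300) fell by 0.95 on the log2 scale, but did not follow the list over the stages between. It stood at 636.5 ± 9.95 CPM at 9W, where the list's mean log2 CPM was highest (4.17). At 17W, where that mean was lowest (2.09), it stood at 1662 ± 86.5 CPM. The list also holds cyclin-dependent kinases, of which Jr6DG00126000 rose from 200.5 ± 4.98 to 1180 ± 84.8 CPM. Without them 62 of 103 members fell and 15 rose (adjusted p = 0.0042, and adjusted p = 0.441 with an estimated correlation). The summed level of the whole list was 5885 ± 69.2 CPM at 8W and 6217 ± 199 CPM at 19W. Of 252 ribosomal proteins 155 fell and 29 rose (adjusted p = 0.000724, and adjusted p = 0.554 with an estimated correlation), while S4-like (Jr5DG00128900) and L26-1 (Jr1DG00004800), at 304 ± 5.87 and 309 ± 1.99 CPM at 8W, did not pass. The summed levels of the secondary wall, cutin and ribosomal lists were 1449 ± 38.5, 9184 ± 147 and 19590 ± 309 CPM at 8W and 1319 ± 41.3, 5412 ± 192 and 15340 ± 261 CPM at 19W. With library sizes alone the S4-like and L26-1 log2 changes were -0.25 and -0.43, and both passed (adjusted p = 0.00153 and 2.35e-05). With upper-quartile factors Jr1DG00004800 passed as well (adjusted p = 0.0012).

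**Figure D2:**
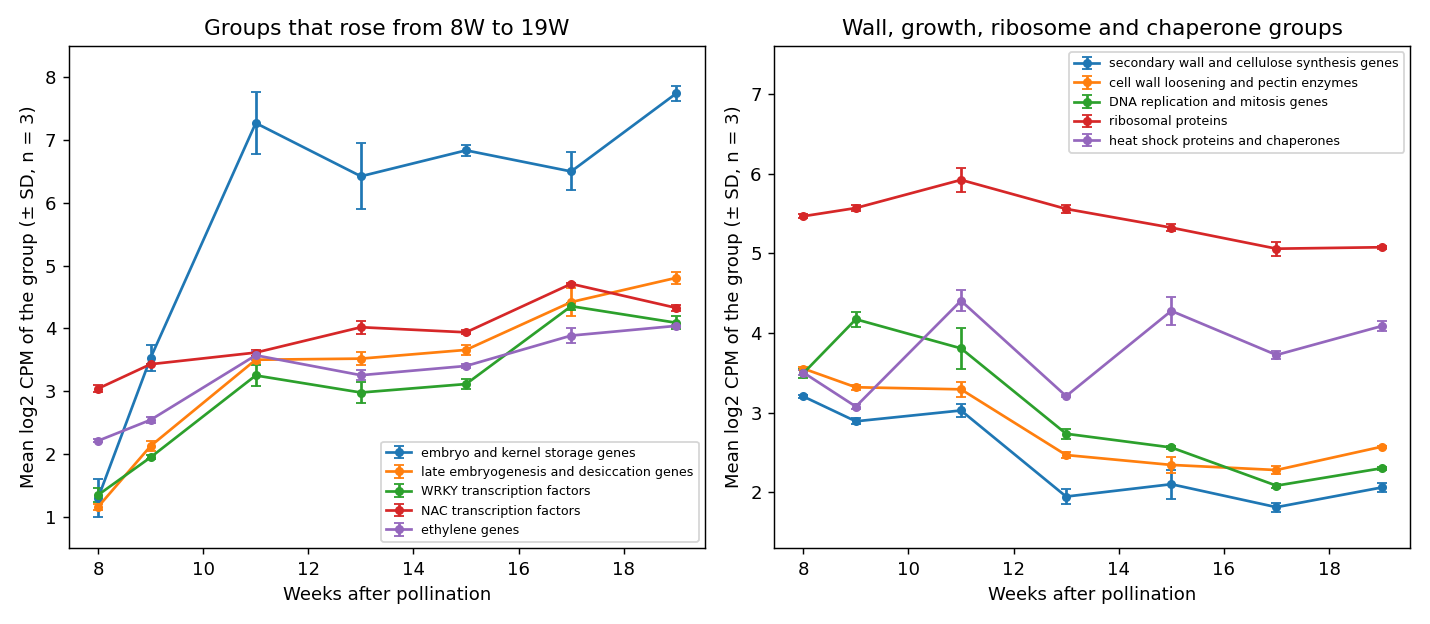
Lines show the mean log2 CPM of each gene group against weeks after pollination, with bars of ± SD over 3 libraries. The embryo and kernel storage group goes from 3.53 at 9W to 7.27 at 11W and 7.75 at 19W (left), and the heat shock group from 3.08 at 9W to 4.40 at 11W, 3.21 at 13W and 4.28 at 15W (right).

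Of 34 flavonoid and proanthocyanidin enzymes 14 rose and 14 fell between 8W and 19W (adjusted p = 0.633), and their median log2 change, 0.22, was -0.11 with library sizes alone. Chalcone synthase (Jr1DG00116500), the entry enzyme of flavonoid synthesis, rose from 14.1 ± 0.807 to 284 ± 33.5 CPM, and flavonoid 3'-monooxygenase (Jr6DG00050300) from 112 ± 6.86 to 524 ± 42.6 CPM. The chalcone synthase gene did not rise steadily: it was highest at 9W, at 327 ± 60.5 CPM, and stood at 54.9 ± 11.1 CPM at 17W. Of 76 phenylpropanoid entry and lignin enzymes 28 rose and 37 fell (adjusted p = 0.148), with cinnamoyl-CoA reductase 1 (Jr7SG00057300) and cinnamyl alcohol dehydrogenase 1 (Jr3DG00011500) up by 0.41 and 0.62 on the log2 scale; with library sizes alone the former was 0.07 (adjusted p = 0.23). Of 34 shikimate pathway and galloylglucose enzymes 10 rose and 20 fell (adjusted p = 0.057, and adjusted p = 0.164 with an estimated correlation). At the preset correlation this list passed with a replicate block (adjusted p = 0.044) and without 8W replicate 1 or 2 (adjusted p = 0.045 and 0.0472). A chorismate mutase (Jr2DG00018700) rose from 130 ± 5.42 to 461 ± 32.2 CPM, and arogenate dehydratase 2 (Jr7DG00102600) fell by 0.37 on the log2 scale. Of 2 polyphenol oxidase genes, the browning enzymes of cut fruit, Jr5DG00051800 rose to 9.07 ± 0.835 CPM at 19W from 0.206 ± 0.153 at 8W and stood at 69.9 ± 6.26 at 13W. Jr5DG00051600 fell from 1.54 ± 0.242 to 0.156 ± 0.132 CPM. The log2 change of the former went from 5.43 to 6.16 without 8W replicate 2, and that of the latter from -3.22 to -4.18 without 19W replicate 3.

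Further groups went both ways and did not pass at 19W against 8W. MYB factors rose in 72 of 145 members and fell in 48 (adjusted p = 0.112), with MYB44-like (Jr8DG00053300) and MYB1R1 (Jr6DG00032200) up by 2.57 and 2.13 on the log2 scale. Of 92 bHLH and TTG1-type regulators 41 rose and 35 fell (adjusted p = 0.942), with a median log2 change of 0.30 and a mean of -0.03; bHLH113 (Jr1DG00186900) and Jr1DG00245400 rose by 0.47 and 1.66, with 0.14 for the former with library sizes alone (adjusted p = 0.256). Photosynthesis genes rose in 28 of 53 members and fell in 12 (adjusted p = 0.239), Rubisco small chain (Jr4DG00190300) and activase (Jr5SG00162700) by 0.49 and 2.42, with 0.16 for the former with library sizes alone (adjusted p = 0.0908). Fatty acid and triacylglycerol synthesis genes rose in 19 of 57 and fell in 28 (adjusted p = 0.485). A stearoyl-ACP desaturase (Jr1DG00212000) fell by 1.97, and an omega-3 desaturase (Jr7DG00071700) rose by 4.12. Sucrose and starch enzymes rose in 46 of 91 and fell in 31 (adjusted p = 0.243), sucrose synthase 1 (Jr4DG00122100) by 0.81. With library sizes alone the list medians of sucrose and starch, senescence, heat shock and proteasome genes turned from 0.23, 0.19, 0.14 and 0.25 to -0.10, -0.15, -0.19 and -0.08.

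Among hormone groups, abscisic acid genes rose in 19 of 32 and fell in 9 (adjusted p = 0.224), with zeaxanthin epoxidase (Jr1DG00017000) up by 1.77 and abscisic acid 8'-hydroxylase 1 (Jr6DG00090000) by 0.82 on the log2 scale. Auxin genes rose in 55 of 109 and fell in 36 (adjusted p = 0.243), IAA29 (Jr4DG00217000) by 9.38, while GH3.9 (Jr4DG00117400) stood at 1512 ± 234 and 1531 ± 91.6 CPM, with a log2 change of -0.32 with library sizes alone (adjusted p = 0.0244). Gibberellin genes rose in 13 of 31 and fell in 14 (adjusted p = 0.239), with a median log2 change of 0 and a mean of -1.13. Ent-kaurenoic acid oxidase Jr7DG00019600 and gibberellin 2-beta-dioxygenase 8 (Jr6DG00184800) rose by 1.05 and 0.67. Jasmonate genes rose in 12 of 28 and fell in 10 (adjusted p = 0.406), TIFY 6B (Jr3SG00057100) and JAZ1 (Jr2DG00197700) by 0.91 and 1.69. Senescence and cell death genes rose in 14 of 32 and fell in 9 (adjusted p = 0.413). Senescence-associated gene 29 (Jr3SG00119500) fell by 0.77 and vacuolar-processing enzyme (Jr8SG00028300) rose by 0.66. The former stood at 1382 ± 203 CPM at 8W and 809 ± 59.8 at 19W, and was highest at 17W, at 1797 ± 128 CPM. Heat shock proteins rose in 45 of 98 and fell in 38 (adjusted p = 0.817), the DnaJ homolog Jr7DG00042300 by 0.73, and HSP90-3 (Jr6SG00140000) stood at 277 ± 8.94 and 286 ± 20.9 CPM, with a log2 change of -0.29 with library sizes alone (adjusted p = 0.00362). Pathogenesis-related genes rose in 30 of 88 and fell in 45 (adjusted p = 0.0921), glucanase 14 (Jr7DG00138800) and class Ib chitinase (Jr1SG00127400) rising by 5.06 and 0.35, with 0.02 for the latter with library sizes alone (adjusted p = 0.789). Glutathione transferases and MATE transporters rose in 38 of 66 and fell in 20 (adjusted p = 0.423); Jr5DG00163500, a heavy metal transport gene, fell by 1.34. The omega-like transferase Jr5DG00073400 had a log2 change of 0.29 (adjusted p = 0.00461), of -0.05 with library sizes alone (adjusted p = 0.638), of 0.08 with upper-quartile factors (adjusted p = 0.409), and of 0.21 and 0.20 without 8W replicate 1 or 19W replicate 3 (adjusted p = 0.0641 and 0.0699). Proteasome subunits rose in 38 of 67 and fell in 14 (adjusted p = 0.36): Jr1SG00081100 fell by 0.29 and beta type-7-B (Jr2SG00030000) rose by 0.42, with 0.09 for the latter with library sizes alone (adjusted p = 0.132).

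Over all genes, 8465 rose and 8433 fell between 8W and 19W in edgeR's test at an adjusted p under 0.05, 4518 and 4734 of them by at least 2-fold. The share of changed genes that rose was 50.1%, 41.7% with upper-quartile factors, and 36.5% with library sizes alone as scaling. Library sizes alone moved the median of all genes to -0.34 (log2) and called 70 genes the opposite way. With TMM this median was -0.00726, so the share follows the scaling and does not show that rises and falls were balanced. Adjusted over the list alone, each list's counts were those over all genes tested, or differed by 1 gene (WRKY factors rose in 48, sucrose and starch enzymes in 47, heat shock proteins in 46 and glutathione transferases in 39). With members at 0 reads set to their bound, list medians moved from -0.66 to -0.64 for mitosis, -0.67 to -0.66 for wall loosening, -0.37 to -0.16 for fatty acid, 0.69 to 0.58 for glutathione transferase and 0.41 to 0.39 for auxin genes.

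**Figure D3:**
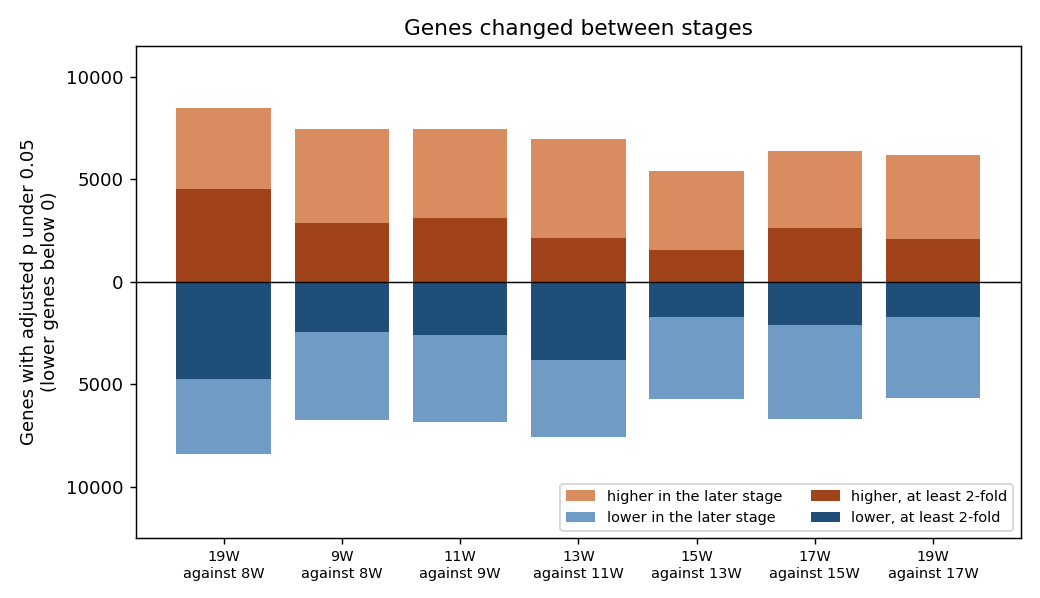
Bars give the number of genes higher (above 0) or lower (below 0) in the later stage of each comparison at an adjusted p under 0.05, with those of at least 2-fold in the darker shade. The 15W against 13W pair has the fewest, 11086 genes, and 19W against 8W the most, 16898.

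Between 8W and 9W, DNA replication and mitosis genes rose in 68 of 120 members and fell in 23 (adjusted p = 0.00925, and adjusted p = 0.588 with an estimated correlation). The largest rises were an Integrase-type DNA-binding protein (Jr4SG00025600; log2 change 8.23 ± 0.381, SE), the clock-linked gene LNK3 (Jr3SG00066200; 4.28 ± 0.883 to 527 ± 71.8 CPM), a GDSL esterase/lipase (Jr2DG00011200), MYB21 (Jr3DG00222200) and CONSTANS-LIKE 1 (Jr2DG00152000; 1.85 ± 0.461 to 78.6 ± 1.23 CPM). L-tryptophan--pyruvate aminotransferase 1, of auxin synthesis (Jr3DG00174800), fell from 78.9 ± 5.78 to 0.182 ± 0.267 CPM. Aspartic proteinase CDR1-like (Jr6DG00186500), ent-kaurenoic acid oxidase (Jr7SG00015200), F-box protein PP2-B15 (Jr4DG00026600) and HOTHEAD (Jr1SG00140400), of cuticle formation, fell, with log2 changes of -8.17, -7.49, -7.01 and -6.72. Without 8W replicate 3 the log2 changes of Jr4SG00025600 and Jr3DG00222200 went from 8.23 and 5.56 to 9.11 and 6.31, and that of Jr3DG00174800, -8.72, was -8.11 without 9W replicate 1 and -11.13 without 9W replicate 2.

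Further groups called up from 8W to 9W were the storage genes (12 of 17 rose, 0 fell), late embryogenesis genes (8 of 16 rose, 0 fell), WRKY factors (26 of 59 rose, 8 fell), NAC factors (26 of 77 rose, 18 fell), flavonoid enzymes (17 of 34 rose, 6 fell) and proteasome subunits (41 of 67 rose, 11 fell), with camera's adjusted p = 0.00925, 0.0167, 0.0162, 0.0269, 0.0302 and 0.0365. With an estimated correlation the late embryogenesis list had adjusted p = 0.389 and the others adjusted p = 0.588. Heat shock proteins fell in 44 of 98 members and rose in 22, and cutin, suberin and wax genes fell in 64 of 135 and rose in 30 (adjusted p = 0.0117 and 0.0351), with adjusted p = 0.588 and adjusted p = 0.389 with an estimated correlation. Adjusted over the list alone, 71 mitosis genes rose and 12 proteasome genes fell, against 68 and 11 over all genes. With members at 0 reads at their bound the storage median moved from 2.67 to 2.52, the WRKY one from 0.64 to 0.56, the cutin one from -0.42 to -0.40 and the heat shock one from -0.37 to -0.35. The proteasome call was lost without 9W replicate 1 (adjusted p = 0.0524). Of the 21707 genes tested, 7468 rose and 6746 fell. The share of NAC factors that rose was no higher than this share over all genes.

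Between 9W and 11W the storage genes rose in 14 of 17 members and fell in 3 (adjusted p = 0.00016, and adjusted p = 0.437 with an estimated correlation). Oil body-associated protein 1A (Jr1SG00075800) went from 0 reads to 34.3 ± 38.6 CPM, at least 214-fold higher, with an SD above its mean. A 14 kDa proline-rich protein DC2.15 (Jr6DG00157500) rose from 0.075 ± 0.0872 to 346 ± 231 CPM. Spermidine hydroxycinnamoyl transferase (Jr5SG00156300) and lipid phosphate phosphatase epsilon 2 (Jr1DG00042500) were at least 118- and 112-fold higher, and a glutathione S-transferase (Jr2SG00047900; 94.2 ± 72 CPM at 11W) 2540-fold (counting interval 732 to 21800). Without 11W replicate 1 the log2 changes of Jr1SG00075800, Jr6DG00157500 and Jr2SG00047900, 11.99, 12.08 and 11.06, were 10.53, 11.36 and 10.20. The lipid-transfer proteins Jr5DG00092500 and Jr5DG00093200 fell from 832 ± 42.5 to 0.38 ± 0.215 CPM and from 412 ± 34.9 to 2.34 ± 0.431 CPM. These genes lie near each other on chromosome 5D, at 9038433 to 9038666 and 9123063 to 9123413, so reads may be shared between copies. A polygalacturonase (Jr1SG00086400), boron transporter 2 (Jr4SG00084600) and peroxidase 29 (Jr1DG00103600) fell, with log2 changes of -8.23, -6.76 and -6.69. The log2 change of Jr1DG00103600 was -10.22 without 11W replicate 2, and that of Jr6DG00157500 13.29 without 9W replicate 3.

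Heat shock proteins rose from 9W to 11W in 59 of 98 members and fell in 14, and ribosomal proteins rose in 167 of 252 and fell in 15 (adjusted p = 1.71e-05 and 3.91e-05), with adjusted p = 0.335 and adjusted p = 0.568 with an estimated correlation. Ethylene genes rose in 51 of 79 and WRKY factors in 34 of 59 (adjusted p = 0.00263 and 0.00608), with adjusted p = 0.335 and adjusted p = 0.437 with an estimated correlation. Phenylpropanoid and lignin enzymes fell in 33 of 76, and proteasome subunits in 33 of 67 (adjusted p = 0.0268 and 0.0497), with adjusted p = 0.335 and adjusted p = 0.568 with an estimated correlation. At 11W, replicate 1 stood apart from replicates 2 and 3, with a chi-square per degree of freedom of 20.8 and 27.0 against them and 5.95 between them, and storage totals of 27970, 15090 and 13240 CPM. Without it 13870 genes changed from 9W to 11W. Adjusted over the list alone, 13 ethylene and 16 ribosomal genes fell and 8 proteasome genes rose, against 12, 15 and 9 over all genes. With members at 0 reads at their bound the WRKY median moved from 0.94 to 0.85 and the ethylene one from 0.87 to 0.85. Mitosis genes fell in 62 of 120 and rose in 23 (adjusted p = 0.0537), and without cyclin-dependent kinases in 58 of 103 (adjusted p = 0.0107, and adjusted p = 0.567 with an estimated correlation). The phenylpropanoid call was lost without 11W replicate 3 (adjusted p = 0.0509) and with library sizes alone (adjusted p = 0.0544). The proteasome call was lost without 9W replicate 1 or 3 or 11W replicate 2 or 3 (adjusted p = 0.0613, 0.0644, 0.0585 and 0.0564). In all, 7440 genes rose and 6859 fell, and the share that rose was 52.0%, or 41.9% with library sizes alone.

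Between 11W and 13W, secondary wall and cellulose synthesis genes fell in 53 of 72 members and rose in 6 (adjusted p = 3.29e-05, and adjusted p = 0.159 with an estimated correlation). The largest falls by fitted log2 change were of the glutathione S-transferase Jr2SG00047900 (94.2 ± 72 to 0.0926 ± 0.107 CPM), gibberellin 20-oxidase (Jr2DG00109700; 639-fold lower, interval 222 to 3140), galactinol synthase 1 (Jr4SG00086300; 759-fold, 138 to 30400), a small class I heat shock protein (Jr7DG00079900; 48.5 ± 15.9 to 0.115 ± 0.106 CPM) and a NIFS-like cysteine desulfurase (Jr2DG00113000; 433-fold, 120 to 3580). Phosphate transporter 1-4 (Jr2DG00249300) was 588-fold higher (interval 103 to 22700). Cyclic dof factor 2 (Jr3SG00102900), a tropinone reductase homolog (Jr7DG00082700), the homeobox gene ATHB-12 (Jr3SG00047400) and LNK3 (Jr3SG00066200) rose by 6.98, 5.73, 5.55 and 5.46 on the log2 scale. Without 11W replicate 1 the log2 changes of Jr2SG00047900 and Jr2DG00109700 went from -9.86 and -9.17 to -9.05 and -8.58, and without 11W replicate 2 that of Jr2DG00249300 from 8.71 to 10.58. Without 13W replicate 2 Jr2DG00109700 and Jr4SG00086300 had -12.39 and -11.05, the latter from -9.14. Without 13W replicate 3 Jr2SG00047900, Jr7DG00079900 and Jr2DG00113000 had -11.09, -9.28 and -11.22, the last of these from -8.52 and Jr7DG00079900 from -8.61.

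Heat shock proteins fell from 11W to 13W in 57 of 98 members, ribosomal proteins in 159 of 252, fatty acid and triacylglycerol genes in 39 of 57, mitosis genes in 78 of 120, and wall loosening enzymes in 67 of 134 (adjusted p = 3.29e-05, 5.93e-05, 0.000466, 0.00143 and 0.00501). With an estimated correlation these had adjusted p = 0.159, 0.589, 0.291, 0.445 and 0.159. At the same step the storage list, the marker of kernel tissue, went from a summed 18770 ± 8020 to 8980 ± 5320 CPM, with 6 of 17 members fallen and 1 risen, and did not pass (adjusted p = 0.306). The 11W total was 27970 CPM in replicate 1, the library that stood apart, and 15090 and 13240 CPM in the others, and without replicate 1 of 11W 13811 genes changed. NAC factors rose in 37 of 77 (adjusted p = 0.00143, and adjusted p = 0.159 with an estimated correlation). Auxin genes rose in 47 of 109 and fell in 38, and camera called them up (adjusted p = 0.0179, and adjusted p = 0.159 with an estimated correlation), with a median log2 change of 0.20 and a mean of -0.07. Adjusted over the list alone, 55 secondary wall, 79 mitosis and 161 ribosomal genes fell and 21 heat shock genes rose, against 53, 78, 159 and 20 over all genes. With members at 0 reads at their bound the wall loosening median moved from -0.69 to -0.64 and the secondary wall one from -1.08 to -1.06. In all, 6974 genes rose and 7587 fell, 2139 and 3825 by at least 2-fold.

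Between 13W and 15W, heat shock proteins rose in 56 of 98 members and fell in 16 (adjusted p = 9.47e-08, and adjusted p = 0.256 with an estimated correlation), among them the small class I heat shock genes Jr7DG00079900 and Jr7DG00080100, with log2 changes of 6.61 ± 0.796 and 7.51 ± 0.707 (SE). These 2 genes are neighbours of like product, so their reads may be shared. Salicylate O-methyltransferase (Jr4DG00050100), Myb domain protein 79 (Jr1DG00191900) and the NIFS-like desulfurase (Jr2DG00113000) were 620-, 439- and 238-fold higher (intervals 211 to 2990, 121 to 3600 and 66 to 1970). A polyvinylalcohol dehydrogenase (Jr3DG00124500) went from 12.6 ± 8.88 CPM to 0 reads, at least 56.8-fold lower. GDSL esterase/lipase 7 (Jr2SG00049700), subtilisin-like protease SBT2.4 (Jr5SG00073100), bZIP factor 2 (Jr4DG00053500) and a WAT1-related protein (Jr5DG00179800) fell, with log2 changes of -5.06, -4.81, -4.75 and -4.65. The log2 change of Jr7DG00080100 was 9.69 without 13W replicate 2 and 6.92 without 15W replicate 2, and that of Jr7DG00079900 was 7.29 without 13W replicate 3 and 5.78 without 15W replicate 2. Those of Jr2DG00113000 and Jr4DG00050100 went from 7.66 to 10.37 without 13W replicate 3 and from 9.10 to 9.95 without 13W replicate 1, and that of Jr2SG00049700 was -7.16 without 15W replicate 3.

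Ribosomal proteins fell from 13W to 15W in 140 of 252 members, auxin genes in 46 of 109 and proteasome subunits in 32 of 67 (adjusted p = 7.07e-05, 0.00992 and 0.0491). With an estimated correlation these had adjusted p = 0.724, 0.256 and 0.719, and the heat shock list adjusted p = 0.256. Adjusted over the list alone, 57 heat shock genes rose and 143 ribosomal genes fell, against 56 and 140 over all genes. The storage list, with 4 of 17 members risen and 3 fallen, did not pass (adjusted p = 0.682) and went from a summed 8980 ± 5320 to 10520 ± 1830 CPM. The proteasome call was lost without 13W replicate 1 or 3 or 15W replicate 3 (adjusted p = 0.0665, 0.0551 and 0.0789). In all, 5381 genes rose and 5705 fell.

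Between 15W and 17W, NAC factors rose in 47 of 77 members, WRKY factors in 43 of 59 and jasmonate genes in 20 of 28 (adjusted p = 4.7e-06, 4.7e-06 and 0.000573). With an estimated correlation these had adjusted p = 0.0682, 0.156 and 0.0911. The storage list, the marker of kernel tissue, went from a summed 10520 ± 1830 to 4834 ± 1280 CPM, with 8 of 17 members fallen and 6 risen, and did not pass (adjusted p = 0.79). A GDSL esterase/lipase APG (Jr1SG00144100) was 208-fold higher (interval 59.6 to 1780), the dehydration-linked BURP protein RD22 (Jr4DG00203700) rose from 8.66 ± 0.526 to 528 ± 188 CPM, and a basic glucan endo-1,3-beta-glucosidase (Jr5DG00038500), 3-ketoacyl-CoA synthase 1 (Jr1SG00051500) and phospholipase D zeta 1 (Jr4DG00026900) rose by 5.68, 5.38 and 5.30 on the log2 scale. A pyruvate decarboxylase family gene (Jr5DG00200000) fell from 587 ± 53.2 to 6.75 ± 1.06 CPM. The NIFS-like desulfurase (Jr2DG00113000), Trichome birefringence-like 37 (Jr5SG00055600), PHD and RING finger protein 1 (Jr8DG00143200) and a small heat shock protein gene (Jr8DG00091100) fell, with log2 changes of -6.66, -6.56, -6.03 and -5.85. The log2 change of Jr1SG00144100 went from 7.52 to 10.30 without 15W replicate 1, and that of Jr2DG00113000 was -7.94 without 17W replicate 2 and -6.06 without 17W replicate 3. Ribosomal proteins fell in 143 of 252 and photosynthesis genes in 19 of 53 (adjusted p = 0.000469 and 0.0147), with adjusted p = 0.627 and adjusted p = 0.468 with an estimated correlation. Adjusted over the list alone, 44 WRKY genes rose and 16 NAC and 144 ribosomal genes fell, against 43, 14 and 143 over all genes. Of the 21707 genes tested, 6352 rose and 6690 fell.

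Between 17W and 19W, photosynthesis genes rose in 31 of 53 members and fell in 3 (adjusted p = 0.000455, and adjusted p = 0.14 with an estimated correlation). The storage list, with 12 of 17 members risen and 2 fallen, did not pass (adjusted p = 0.212) and went from a summed 4834 ± 1280 to 21290 ± 2610 CPM. A pectinesterase (Jr3SG00056100) went from 0 reads to 13.3 ± 1.14 CPM, at least 58.4-fold higher. The NIFS-like desulfurase (Jr2DG00113000) rose from 0.107 ± 0.125 to 18.6 ± 2.43 CPM. Transport and Golgi organization 2 homolog (Jr4SG00073200), a hyoscyamine 6-dioxygenase-like gene (Jr6SG00083900) and the receptor kinase PXL2 (Jr2DG00255600) rose by 6.02, 5.46 and 5.01 on the log2 scale. Glucose-6-phosphate translocator 2 (Jr5DG00081300), NAC 86-like (Jr6SG00072600), nodulation-signaling pathway 2 (Jr5DG00201300) and NAC 29 (Jr3SG00128300) fell, with log2 changes of -5.36, -4.17, -3.40 and -3.35, and calcium-binding CML45 (Jr2DG00022400) fell from 47.4 ± 7.48 to 1.69 ± 0.407 CPM. The log2 change of Jr2DG00113000, 7.40, was 8.69 without 17W replicate 2 and 6.80 without 17W replicate 3, that of Jr6SG00083900 6.06 without 17W replicate 3, and that of Jr6SG00072600 -4.79 without 19W replicate 1. In all, 6182 genes rose and 5657 fell, and the share that rose was 52.2%, or 41.6% with library sizes alone. Consecutive comparisons share the libraries of the stage between them, so their changes are not independent.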

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

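The alternatives with library sizes alone, without the 11W libraries, without storage and late embryogenesis genes, and without cyclin-dependent kinases were chosen after seeing the data. Under each alternative run, the 8 counts of changed genes stayed within 1.5 times the reported ones. These counts cover 51.1% to 97.7% of the genes tested, so most had little room to rise, and this is a weak check. All 80 named-gene entries kept direction and call wherever they were recomputed, though leaving out 1 library moved the fold of 29 of them by over 1.5 times. The 56 list genes kept their call over stages. Between 8W and 19W, 5 called list genes lost the call with library sizes alone, and Jr5DG00073400 turned to -0.0457 and also lost it with upper-quartile factors and without 8W replicate 1 or 19W replicate 3. Uncalled changes turned sign for Jr4DG00117400 (-0.0174 with RLE factors, -0.0174 with DESeq2, -0.19 with upper-quartile factors, -0.32 with library sizes alone, and from -0.13 to 0.143 with 1 library left out), Jr6SG00140000 (-0.16 with upper-quartile factors, -0.29 with library sizes alone, from -0.0109 to 0.0649 with 1 library left out), Jr2SG00187000 (-0.00232 and -0.13 with those scalings) and Jr5DG00128900 (-0.13 and -0.25 with them). The cause was not tested. Among the 61 list results recomputed no test changed direction, but the medians of 5 uncalled lists turned sign with library sizes alone. With a 4-fold range, 6.09% of genes were highest at 13W and 4.45% at 15W, and the cause was not tested. Replicate numbers did not pair the libraries: correlations of same-numbered deviations ran from -0.123 to 0.0833, and 7 of 21 libraries correlated best with their own number. With a replicate block 21186 genes changed over stages and 16879 between 8W and 19W, with 16804 of the 16898 calls of the latter shared. Among the list, named-gene and list-gene results the block altered 1 call, the shikimate list (adjusted p = 0.044). That list also passed without 8W replicate 1 or 2 (adjusted p = 0.045 and 0.0472), and had adjusted p = 0.164 with an estimated correlation. With an estimated correlation 40 list calls were lost. The 15W proteasome call was lost with RLE factors (adjusted p = 0.05) and with the 1 CPM filter (adjusted p = 0.0507), and the 11W one with that filter (adjusted p = 0.0519). With library sizes alone MYB factors passed (adjusted p = 0.0293), and with TMM they had adjusted p = 0.0808 with an estimated correlation. Upper-quartile factors moved the median of all genes at 19W against 8W to -0.22 (log2). Library sizes alone moved it to -0.12 at both 11W against 9W and 13W against 11W. Without the 11W libraries 20938 genes changed over stages, and without storage and late embryogenesis genes 21162. The alternative for normalized values was not run, since counts were used. With 3 libraries per stage, 31 of 50 simulated 1.5-fold rises were recovered, in a simulation where few genes were changed.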

Other observations

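The storage co-deviation, 11W ratio, top-gene share and Rubisco activase tests were chosen only after related results were seen, and the clock genes were tested because LNK3 and Rubisco activase had been seen to alternate. Clock genes, chosen by name outside the fixed lists, swung between stages. The dawn-phased gene LHY (Jr1DG00089700) stood at 16.6 CPM at 8W, 291 at 9W, 17.2 at 11W, 165 at 13W, 105 at 15W, 56.1 at 17W and 204 at 19W. The copies Jr1SG00053800 and Jr1SG00053700 spanned 16.9- and 18.4-fold. Evening gene TOC1 (Jr6DG00046500) stood at 75.1 CPM at 8W, 24.3 at 9W and 95.5 at 13W, while the ELF4-like genes Jr2SG00144300 and Jr1SG00137100, also taken as evening genes, stood at 5.33 and 7.71 CPM at 8W, 17.5 and 7.90 at 9W and 5.016 and 5.005 at 13W. Rubisco activase (Jr5SG00162700) stood at 526 ± 70.5 CPM at 11W, 143 ± 1.8 at 13W and 760.5 ± 60.7 at 15W.

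These swings may come from stages being collected at different times of day, which the labels do not give. Over 7 stage means, 8 dawn genes and 3 evening genes gave Pearson r = -0.329 (exact permutation p = 0.441, adjusted 0.527) and Spearman rho = -0.321 (exact permutation p = 0.498, adjusted 0.746). Without the 2 stages farthest from the median r was 0.242. This r meets neither bound set for it, below -0.5 or above 0, so time of day and development cannot be told apart here, with 7 stage means and no collection times in the labels. The evening mean pools TOC1 with 2 ELF4-like genes, of which Jr2SG00144300 went the opposite way to TOC1 from 8W to 9W.

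The storage transcripts in the pellicle may come from kernel tissue carried over in different amounts. The 17 storage genes deviated together within stages: their mean pairwise correlation, 0.39, was above 100% of 1000 random gene sets matched on mean expression (5th to 95th percentile -0.0316 to 0.0648), but genes regulated together would do so under any source of uneven libraries, so this does not single out carry-over. The 10 genes with the most reads held at most 6.44% of a library's counts, which argues against a few genes taking most of them, while a further test, 16895 other genes changed with storage genes removed before scaling against 16882, decides nothing about scaling, since a count over most genes tested could hardly move. If all transcripts of these genes came from a single source, each gene would have the same ratio between the 11W libraries. Their storage totals were 27970, 15090 and 13240 CPM. Over 15 genes the log2 ratio of the highest to the lowest library had a median of 0.94 and an SD of 0.506. This SD lay between the bounds set for a single source (under 0.5) and against it (over 1). It cannot decide on carry-over: genes also expressed in the pellicle would differ in ratio, and genes regulated together would share one. Probable peroxygenase 4 (Jr3DG00180900) and Glutelin type-A 1 (Jr3DG00195100) had log2 ratios of -0.17 and -0.362, and every other gene had 0.47 or more. The SD without these genes was not computed. Carry-over stays open, as do fruits of unequal age within a stage and expression in the pellicle itself, which were not tested.

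The alternating heat shock group may follow storage tissue, or weather and hour at collection: within stages, storage and heat shock deviations gave r = 0.192 (95% interval -0.355 to 0.641, permutation p = 0.527, adjusted 0.527; Spearman rho = 0.0156, permutation p = 0.955, adjusted 0.955; r = 0.063 without the 2 farthest libraries), under the bound of 0.2 set in advance for excluding carry-over. That the whole interval lie under this bound was required only after r was seen, and by that rule carry-over stays open. Over 7 stage means Rubisco activase and the heat shock group gave Spearman rho = 0.643 (exact permutation p = 0.139, adjusted 0.417) and Pearson r = 0.662 (exact permutation p = 0.114, adjusted 0.343). It rests on the 2 farthest stages, without which r was 0.127. In all 3 relations were computed, and collection conditions cannot be told apart from stage.

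In 60 groupings of the 21 libraries, only the real one gave as many as 21214 genes, and the highest other gave 8. Shuffled groupings mix libraries of different stages, whose differences then widen the spread, so low counts were bound to follow. The result shows that libraries group by stage, and it cannot exclude differences between single samples or batches. For each pair of stages 10 splits exist, too few for a share under 0.05. The real counts and highest others were 16898 and 0 for 19W against 8W, 14214 and 1 for 9W against 8W, 14299 and 0 for 11W against 9W, 14561 and 0 for 13W against 11W, 11086 and 0 for 15W against 13W, 13042 and 0 for 17W against 15W, and 11839 and 0 for 19W against 17W.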
